A study of Homo sapiens with 24 samples.

How the data were processed

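Transcripts of 189 endogenous genes, most of them with roles in the cell cycle, were counted on the nCounter platform in 24 libraries, together with 6 positive and 8 negative control probes. Per the labels, HCT116 cells were transfected with 50 nM and PC3 cells with 100 nM siRNA using Lipofectamine RNAiMAX, and total RNA was extracted with TRIZOL. The labels define 8 groups of 3 libraries, 6 in HCT116 and 2 in PC3, and 0 columns belonged to no library. The labels do not say that replicates were separate cultures, so the p-values measure the spread between samples, which is possibly technical. The sequences of the siRNAs, the instrument runs and the upstream image processing are not given in the sources used here.

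The group tables of 7 groups hold molecule counts as deposited. The deposited table of PC3 siCARLo-1 v2&4 holds a score instead of a raw count, namely values already scaled by the positive controls, since the positive control sum is 13061 in each of its 3 libraries. The series-wide table likewise holds a score that the authors made by scaling counts with the positive controls, and it served as an alternative. In that table the positive control sums fall into 4 sets, namely 8964 to 8967 for HCT116 siCTRL, 12210 to 12212 for HCT116 siCARLo-1 v3, siCARLo-3 and siCARLo-4, 16033 to 16034 for HCT116 siCARLo-5, siCARLo-7 v2 and PC3 siCTRL, and 13061 for PC3 siCARLo-1 v2&4. Therefore no siCARLo group shares a set with its control, and if the sets mark instrument runs, group and run cannot be told apart in any comparison with a control.

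Probe names were taken from the deposited tables. Of their accessions 178 matched the human RefSeq gene table and 11 did not, and 2 matched another symbol (MRE11A as MRE11, NACAP1 as NACA4P). No genome build is named in the sources used here, so no coordinates are given. Transcripts of PTTG1 and PTTG2, and of NACA and NACAP1, are nearly identical, and which of each pair a probe counts is uncertain. The probes named NACA and NACAP1 did not behave alike. Their mean normalized counts in HCT116 siCARLo-1 v3 were 41.2 and 3599, and their log2 levels in the PC3 control 5.98 and 11.35. Among the HCT116 siCARLo groups NACA was called up in 4 and down in 0, and NACAP1 up in 1 and down in 1. Rises given for NACA are thus those of the probe with low counts.

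Endogenous counts per library ranged from 55893 to 236508 among the libraries with raw counts, and 167 to 184 genes per library lay above background. Background was the mean plus 2 SD of the negative probes and ranged from 4.64 to 16.1 counts. A gene was tested if it lay above background in at least 3 libraries of the fit. The files mark no gene as housekeeping, so library sizes were scaled with TMM over all endogenous genes, the fallback chosen before the data were examined. TMM factors ranged from 0.927 to 1.11 in HCT116 and from 0.966 to 1.03 in PC3. Each fold change is thus relative to the bulk of the panel, and a change shared by most panel genes would not be seen.

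HCT116 comparisons used the edgeR quasi-likelihood F test on raw counts of all 18 HCT116 libraries, with a common dispersion of 0.00828, a coefficient of variation of 9.10% between replicates. Because 1 PC3 group holds scaled values, limma on log2 of the TMM-scaled value plus 1 was used for the 6 PC3 libraries and for the fits over all 24 libraries, as the design had set for values that are not counts. P-values were adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Values after ± are standard errors beside a log2 fold change and SDs beside a mean, with n = 3 libraries per group. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

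The comparisons were each siCARLo group with the control of its line, an F test among the 5 HCT116 siCARLo groups, genes called the same way in all 5, the HCT116 siCARLo-1 v3 effect minus the PC3 siCARLo-1 v2&4 effect, and the PC3 control with the HCT116 control. Comparisons within a set of equal positive control sums were added after the data were seen. For genes called in the same direction, unchanged groups were simulated against the same 3 controls in 100 draws. The samples were also regrouped in all 10 possible ways for 3 against 3 libraries, and in 100 drawn ways, the real grouping among them, for the larger designs.

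Gene lists were fixed before the data were examined and tested with limma camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with at least 3 tested members. The lists were G1/S and E2F target genes (22 members, 18 on the panel), origin licensing and firing (20, 18 on the panel), G2/M and mitotic genes (26, 15 on the panel), spindle assembly checkpoint and separase (12, 10 on the panel), and APC/C and SCF ubiquitin ligase subunits (21, 16 on the panel). The others were CDK inhibitors (8, 7 on the panel), p53 target genes (17, 4 on the panel), DNA damage checkpoint and repair (19, 8 on the panel), G1 cyclins with their CDKs and the pocket protein network (17 of 17), TGF-beta and SMAD (6 of 6) and 14-3-3 proteins (7 of 7). Of the 7 cohesin subunits the panel holds 1, SMC1A, so that list was not tested. Lists overlap, since SFN for example belongs to the p53 target and the 14-3-3 lists, and camera compares a list with the other genes of this panel.

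Genes were named by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among called genes whose 3 libraries all lay outside the range of the 3 controls, a range condition that was dropped for the difference of effects and for the F test. It also took MYC, CDKN1A, CDKN1B, CCND1, CCNE1, CDK1 and E2F1 whatever their test, and up to 4 called members per list. Some genes that the rule picked are not reported here and are left out of the counts of named gene results, though they stayed in every fit, count and list test. The text prints most of the other genes, and other list members only where a list is described.

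The edgeR and limma steps were tested on simulated data with 40 changed genes in each of 10 draws. For HCT116 (178 genes) 78.4% of genes changed 1.5-fold and 95.5% of those changed 2-fold were recovered, and 0.655% of unchanged genes were called. For PC3 (176 genes) the shares were 89.4%, 98.0% and 1.74%. For the comparison of the lines (183 genes) they were 83.4%, 94.0% and 0.905%, and for the difference of effects (183 genes) 55.0%, 89.9% and 0.626%. The simulated changes were balanced between rises and falls, and most genes stayed unchanged. In the PC3 data 136 of 179 genes were called, so these shares do not cover a change of most of the panel.

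Alternatives planned before the data were examined were DESeq2 size factors, positive control scaling, no filter or a filter in every library, adjustment over the HCT116 comparisons together, a replicate block, fits of only the groups compared, leaving out each library, the series-wide table, DESeq2 and limma on counts, background subtraction, and for lists an estimated correlation and fry. Chosen after the data were seen were scaling by 6 reference genes (CLTC, GAPDH, GUSB, HPRT1, PGK1 and TUBB), HCT116 siCTRL libraries 1 and 2 as 1 library, and edgeR on the whole numbers for fits that include PC3. The 2 control libraries were merged in that alternative because their profiles were close (chi-square per degree of freedom 1.18, p = 0.0495, against 2.93 and 2.92 for the other control pairs). DESeq2 was not run for fits that need PC3 siCARLo-1 v2&4. The 6 reference genes were not all stable with TMM. In PC3 siCARLo-1 v2&4, TUBB (log2 fold change -1.26), CLTC (0.64), GUSB (-0.41) and HPRT1 (-0.35) were called, while GAPDH and PGK1 were not. The F test among the HCT116 siCARLo groups called TUBB (adjusted p = 1.7e-07), HPRT1 (2.4e-06), GAPDH (0.0036), CLTC (0.024) and PGK1 (0.044), but not GUSB (0.11). A call lost under that scaling may thus come from the reference genes.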

Results

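The panel measured cell cycle transcripts in the colon cancer line HCT116 and the prostate cancer line PC3 after siRNA transfection. In HCT116, 5 groups received siRNAs against CARLo transcripts (siCARLo-1 v3, siCARLo-3, siCARLo-4, siCARLo-5 and siCARLo-7 v2) and 1 group a control siRNA. In PC3, 1 group received siCARLo-1 v2&4 and 1 group a control siRNA, and each of the 8 groups had 3 libraries. Per the series title the targets are long non-coding RNAs of 8q24.21. No probe for a target is on the panel, so knockdown could not be checked in any library, and each comparison shows what followed transfection of an siRNA. MYC, a gene of that chromosomal region, is on the panel and is given for every comparison. A value in parentheses after a gene name is its log2 fold change unless it is marked otherwise.

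Total endogenous counts per library were 89835 to 130777 for HCT116 siCTRL, 83850 to 136781 for siCARLo-1 v3, 55893 to 92559 for siCARLo-3, 133885 to 195475 for siCARLo-4, 128465 to 175266 for siCARLo-5 and 108874 to 125751 for siCARLo-7 v2. They were 216562 to 236508 for PC3 siCTRL, and the scaled values of PC3 siCARLo-1 v2&4 summed to 73568 to 82152. Endogenous molecules per positive control count were 10.8 ± 0.998 in HCT116 siCTRL and lower in each siCARLo group (9.21 in siCARLo-1 v3, 7.54 in siCARLo-3, 9.64 in siCARLo-4, 8.59 in siCARLo-5 and 9.79 in siCARLo-7 v2), and 10.4 ± 0.939 in PC3 siCTRL against 5.96 ± 0.329 in PC3 siCARLo-1 v2&4. These ratios depend on the RNA loaded, which is not given in the sources used here. The ratio of the spiked positive controls A and B, which no siRNA acts on, also differed between groups. It was 2.01 ± 0.16 in HCT116 siCTRL and 2.42, 2.69, 2.19, 2.37 and 2.90 in siCARLo-1 v3, siCARLo-3, siCARLo-4, siCARLo-5 and siCARLo-7 v2. Single libraries of siCARLo-1 v3 and siCARLo-4 lay within the range of the HCT116 controls. In PC3 the ratio was 2.35 and 1.97 in siCTRL and siCARLo-1 v2&4. A technical shift of single probes between groups is thus present for these controls, and fold changes of that size are not separated from one here.

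What siCARLo-1 v3 changed in HCT116 was asked first. CDKN1A, which encodes the CDK inhibitor p21, rose most, from 317 ± 19.5 to 1626 ± 177 normalized counts (2.36 ± 0.08, 5.14-fold, adjusted p = 1.2e-14). The cyclin D1 gene CCND1 (1.01 ± 0.05, adjusted p = 5.8e-11), the 14-3-3 sigma gene SFN (1.04 ± 0.08, adjusted p = 1.4e-08) and MYC (0.77 ± 0.06, adjusted p = 8.6e-09) also rose, while cyclin A2 CCNA2 (-1.22 ± 0.14, 2.33-fold lower, adjusted p = 3.2e-06), securin PTTG1 (-1.06 ± 0.09, adjusted p = 6.1e-08) and the mitotic kinase PLK1 (-1.00 ± 0.14, adjusted p = 2.6e-05) fell. Further rises were CCNB3 (1.30), near background in the controls, ANAPC2 (0.80), the NF-kappaB genes NFKBIA (0.65) and RELA (0.64), and CCNE2 (0.65). Further falls were PTTG2 (-0.99), the checkpoint kinases BUB1 (-0.94) and BUB1B (-0.81), the mitotic cyclins CCNB2 (-0.79) and CCNB1 (-0.73), and RB1 (-0.76). TGFB3 was at least 1.61-fold lower (adjusted p = 0.036) and lost its call without any 1 of the 3 controls or siCARLo-1 v3 replicate 1 or 2 (adjusted p 0.051 to 0.12), with 6 reference genes (0.060) or with control libraries 1 and 2 as 1 library (0.055).

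Of the other fixed genes, the cyclin E1 gene CCNE1 (0.54, adjusted p = 0.0017) rose and CDK1 (-0.50, adjusted p = 0.0042) fell, whereas CDKN1B (-0.18, adjusted p = 0.36) and E2F1 (0.22, adjusted p = 0.25) were not called. E2F1 was called without siCARLo-1 v3 replicate 3 (0.38, adjusted p = 0.028). The call of CCNE1 was lost with positive control scaling (0.50, adjusted p = 0.054), and that of CDK1 with scaling by 6 reference genes (-0.34, adjusted p = 0.13).

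The p53 target list was higher (4 up, 0 down and 0 not called of 4, 4 and 0 adjusted over the list alone), with GADD45A (0.53) and MDM2 (0.46) beside CDKN1A and SFN, camera adjusted p = 1.6e-08 and adjusted p = 3.3e-04 with an estimated correlation. G2/M genes were lower (0 up, 9 down and 5 not called of 14, 0 and 11 adjusted over the list alone), such as CCNA2, PLK1 and BUB1, camera adjusted p = 3.4e-05, but adjusted p = 0.28 with an estimated correlation. Replicate 3 of siCARLo-1 v3, which stands apart from the others, lay lower in several of these genes. Without it 8 were down and the list was still called (mean -0.50 against -0.64, adjusted p = 1.0e-04). The spindle checkpoint list was lower too (1 up, 6 down and 3 not called of 10, 1 and 7 adjusted over the list alone, for example BUB1 and BUB3 (-0.38)), camera adjusted p = 0.0051, but adjusted p = 0.31 with an estimated correlation. Origin licensing genes were not called as a list (0 up, 10 down and 7 not called of 17, 0 and 10 adjusted over the list alone, camera adjusted p = 0.062), though ORC1 (-0.73), CDC7 (-0.70), DBF4 (-0.64) and MCM4 (-0.57) fell. That list was called without siCARLo-1 v3 replicate 1 (adjusted p = 0.031) or 2 (adjusted p = 0.035). The same holds for CDK inhibitors (2 up, 1 down and 4 not called of 7, 2 and 1 adjusted over the list alone, camera adjusted p = 0.060, with CDKN2B (0.75) up and CDKN2D (-0.40) down), called at 0.031 without replicate 1 and 0.023 without replicate 2. CDKN2B lay 1.17 higher in replicate 3 than in the others, and without that library the list had 1 up and 1 down (adjusted p = 0.059). The remaining lists were not called. G1/S genes had 3 up and 7 down of 18 (list alone 3 and 8, adjusted p = 0.32), and 5 up and 6 down without replicate 3. Ubiquitin ligase subunits had 1 up and 4 down of 16 (list alone 1 and 4, adjusted p = 0.77). DNA damage genes had 0 up and 1 down of 7 (list alone 0 and 1, adjusted p = 0.75). G1 cyclins and pocket proteins had 4 up and 3 down of 16 (list alone 4 and 3, adjusted p = 0.29). TGF-beta and SMAD had 1 up and 1 down of 6 (list alone 1 and 1, adjusted p = 0.75). 14-3-3 proteins had 1 up and 1 down of 7 (list alone 1 and 1, adjusted p = 0.75).

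By edgeR 73 of 178 genes were called for siCARLo-1 v3, 30 up and 43 down, 31 of them by at least 1.5-fold. Positive control scaling gave 46 (17 up, 29 down), 6 reference genes gave 51 (34 up, 17 down, median of all genes 0.14) and the series-wide values 53 (44 up, 9 down, median 0.27). The fall of G2/M genes held under these scalings of the raw counts, with 8 of 14 down under positive controls and 7 of 14 under reference genes, while origin licensing genes had 6 and 3 of 17 down.

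For siCARLo-3 in HCT116 the rises included p53 target genes. CDKN1A (2.51 ± 0.08, 5.69-fold, adjusted p = 5.5e-15), the stress gene GADD45A (1.44 ± 0.08, 2.72-fold, adjusted p = 4.5e-11) and MDM2 (0.93 ± 0.10, adjusted p = 2.7e-07) were all higher. The growth regulators CCND1 (1.26 ± 0.06, adjusted p = 1.6e-12) and JUN (1.75 ± 0.23, adjusted p = 6.0e-06) rose as well, whereas E2F1 (-1.78 ± 0.21, 3.43-fold lower, adjusted p = 1.3e-06), a driver of S phase entry, fell from 122 to 35.9. The APC/C subunit gene CDC23 (-1.69 ± 0.11, adjusted p = 2.6e-10) and replication genes CDC45 (-1.47) and CDC7 (-1.32) fell too. Other rises were NACA (1.32), CCND3 (1.27) and, near background in the controls, TGFB2 (1.19), and CDC14C was at least 1.60-fold higher (adjusted p = 0.0032). Other falls were ATF6B (-1.50), the F-box gene SKP2 (-1.35), NEK1 (-1.22), E2F4 (-1.19) and the pocket protein genes RBL2 (-1.17) and RBL1 (-1.01). Values without a call were MYC (-0.06, adjusted p = 0.43), CDKN1B (0.15, adjusted p = 0.43) and CDK1 (-0.17, adjusted p = 0.27), although positive control scaling called MYC (-0.44, adjusted p = 0.014) and CDK1 (-0.57, adjusted p = 0.0062) lower. CCNE1 (-0.38, adjusted p = 0.034) fell, a call lost without control replicate 1 (adjusted p = 0.055) or 3 (0.071) or siCARLo-3 replicate 1 (0.059) or 2 (0.15).

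Among the lists only p53 target genes were called for siCARLo-3, and higher (4 up, 0 down and 0 not called of 4, 4 and 0 adjusted over the list alone, camera adjusted p = 8.3e-09, adjusted p = 4.8e-04 with an estimated correlation). The 14-3-3 genes divided (5 up, 2 down and 0 not called of 7, 5 and 2 adjusted over the list alone, camera adjusted p = 0.23), with YWHAB (1.10) and YWHAE (0.62) up and YWHAH (-0.81) down. DNA damage genes had only falls (0 up, 3 down and 4 not called of 7, 0 and 3 adjusted over the list alone, camera adjusted p = 0.36), such as BRCA1 (-0.93) and PRKDC (-0.41). Origin licensing (2 up, 7 down and 8 not called of 17, 2 and 7 adjusted over the list alone, camera adjusted p = 0.23) held ORC1 (-0.69) and MCM4 (-0.63). The G2/M list (1 up, 6 down and 7 not called of 14, 1 and 6 adjusted over the list alone, camera adjusted p = 0.36) held ESPL1 (-0.81), BUB1B (-0.80) and PKMYT1 (-0.63) on the lower side and MAD2L1 (0.59) on the higher. The remaining lists were not called. G1/S genes had 2 up and 7 down of 18 (list alone 2 and 7, adjusted p = 0.23). The spindle checkpoint list had 2 up and 3 down of 10 (list alone 2 and 3, adjusted p = 0.76). Ubiquitin ligase subunits had 4 up and 5 down of 16 (list alone 5 and 5, adjusted p = 0.36). CDK inhibitors had 1 up and 0 down of 7 (list alone 1 and 0, adjusted p = 0.23). G1 cyclins and pocket proteins had 6 up and 5 down of 16 (list alone 6 and 6, adjusted p = 0.60). TGF-beta and SMAD had 2 up and 1 down of 6 (list alone 2 and 2, adjusted p = 0.93).

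The edgeR test called 93 of 178 genes for siCARLo-3 (45 up, 48 down), 55 by at least 1.5-fold. Positive controls gave 99 (17 up, 82 down, median of all genes -0.39), 6 reference genes 86 (27 up, 59 down, median -0.15) and the series-wide values 81 (24 up, 57 down, median -0.17). The p53 target list kept 3 of 4 members up under positive controls, while the 14-3-3 genes turned to 1 up and 2 down. Some lists that went both ways with TMM went mostly down with positive controls, such as ubiquitin ligase subunits (0 up and 9 down, 1 and 7 with reference genes), G1 cyclins and pocket proteins (2 and 6) and the spindle checkpoint list (0 and 4).

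After siCARLo-4 in HCT116 fewer genes were called with a change of at least 1.5-fold (20) than in the other siCARLo groups of that line (29 to 55). The transcription factor gene JUN (1.73 ± 0.21, 3.32-fold, adjusted p = 1.0e-05), CDKN1A (1.23 ± 0.07, 2.35-fold, adjusted p = 6.7e-10), the phosphatase gene CDC25B (0.93 ± 0.07, 1.91-fold, adjusted p = 1.7e-08) and CCND1 (0.69 ± 0.05, 1.62-fold, adjusted p = 1.7e-08) rose. MYC fell (-0.44 ± 0.06, 1.35-fold lower, adjusted p = 2.8e-05), and so did the origin-firing kinase CDC7 (-0.86 ± 0.17, 1.82-fold lower, adjusted p = 9.0e-04) and the break repair genes RAD50 (-0.81) and MRE11A (-0.72). Further rises were NACA (0.91), ABL1 (0.69), CDH1 (0.66) and CDC34 (0.67), the last not called under positive control scaling (0.49, adjusted p = 0.063). Further falls were RBL1 (-0.73), BRCA1 (-0.63), CCNH (-0.55) and SMAD4 (-0.53). Not called were CDKN1B (0.09, adjusted p = 0.60) and CCNE1 (0.18, adjusted p = 0.27).

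Several siCARLo-4 calls lay near the threshold and were lost when 1 library was left out, mostly at folds of similar size. E2F2 (0.90, adjusted p = 0.0064) lost its call without control replicate 1 (0.68, adjusted p = 0.055), and CDKN2B (0.74, adjusted p = 0.030) without control replicate 1 or 3 or any 1 siCARLo-4 replicate (0.65 to 0.76, adjusted p 0.058 to 0.096). NEK1 (-0.75, adjusted p = 0.020) lost it without control replicate 1 or 2 or siCARLo-4 replicate 3 (-0.59 to -0.74, adjusted p 0.058 to 0.11). CDK6 (-0.63, adjusted p = 0.022) lost it without control replicate 1 or 2 or siCARLo-4 replicate 2 or 3 (-0.57 to -0.63, adjusted p 0.058 to 0.085), and CCNE2 (-0.52, adjusted p = 0.024) without control replicate 1 or siCARLo-4 replicate 1 or 3 (-0.44 to -0.49, adjusted p 0.073 to 0.11). CDK1 (-0.36, adjusted p = 0.032) lost it without control replicate 1 or 2 or siCARLo-4 replicate 1 or 3 (-0.31 to -0.37, adjusted p 0.070 to 0.12). With control libraries 1 and 2 as 1 library CDK6 (adjusted p = 0.053), CCNE2 (0.054) and CDK1 (0.091) were not called either. E2F1 (0.48, adjusted p = 0.014) lost it without control replicate 3 (0.38, adjusted p = 0.063) or siCARLo-4 replicate 2 (0.41, adjusted p = 0.064). With positive control scaling E2F1 was not called (0.34, adjusted p = 0.22), nor with 6 reference genes (0.48, adjusted p = 0.055), which also left CDK1 (-0.36, adjusted p = 0.12) and CCNE2 (-0.52, adjusted p = 0.079) without a call.

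No list was called for siCARLo-4. P53 target genes (2 up, 0 down and 2 not called of 4, 2 and 0 adjusted over the list alone, camera adjusted p = 0.090) held SFN (0.56), 14-3-3 genes (4 up, 1 down and 2 not called of 7, 4 and 2 adjusted over the list alone, camera adjusted p = 0.50) YWHAH (0.41) and YWHAZ (0.33) up and YWHAE (-0.33) down, and origin licensing (0 up, 5 down and 12 not called of 17, 0 and 5 adjusted over the list alone, camera adjusted p = 0.24) MCM6 (-0.45) and ORC1 (-0.42). G2/M genes were mixed (3 up, 4 down and 7 not called of 14, 3 and 4 adjusted over the list alone, camera adjusted p = 0.80), with PKMYT1 (0.49) and ESPL1 (0.47) up and BUB1B (-0.47) down. With 6 reference genes the falls lost their calls (3 up, 0 down), while the median of the list stayed at 0.05. With positive controls no 14-3-3 gene was called higher (0 up, 1 down), and G2/M genes had 1 up and 4 down. G1/S genes had 2 up and 4 down of 18 (list alone 2 and 4, adjusted p = 0.51). The spindle checkpoint list had 2 up and 3 down of 10 (list alone 2 and 3, adjusted p = 0.52). Ubiquitin ligase subunits had 1 up and 3 down of 16 (list alone 1 and 3, adjusted p = 0.61). CDK inhibitors had 2 up and 0 down of 7 (list alone 2 and 0, adjusted p = 0.24). DNA damage genes had 0 up and 2 down of 7 (list alone 0 and 2, adjusted p = 0.24). G1 cyclins and pocket proteins had 3 up and 4 down of 16 (list alone 5 and 4, adjusted p = 0.87). TGF-beta and SMAD had 0 up and 1 down of 6 (list alone 0 and 1, adjusted p = 0.50). In all, edgeR called 63 of 178 genes for siCARLo-4 (32 up, 31 down), 20 by at least 1.5-fold. Scaling to positive controls gave 43 (11 up, 32 down, median of all genes -0.15) and the series-wide values 51 (50 up, 1 down, median 0.25).

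In HCT116 with siCARLo-5, BRCA1 (-1.35 ± 0.19, 2.55-fold lower, adjusted p = 1.2e-05) and MRE11A (-1.02) of break repair, the checkpoint kinases CHEK1 (-1.14) and ATR (-0.95), the polymerase subunit gene POLE2 (-1.21) and the cohesin gene SMC1A (-1.15 ± 0.08, 2.22-fold lower, adjusted p = 1.4e-09) were lower. Higher were CDKN1A (1.52 ± 0.07, 2.86-fold, adjusted p = 2.1e-11), SFN (1.06 ± 0.08, 2.09-fold, adjusted p = 7.6e-09) and CCND1 (0.76 ± 0.05, 1.70-fold, adjusted p = 2.9e-09). MDM2 (-0.50 ± 0.10, adjusted p = 3.3e-04) fell, unlike in siCARLo-1 v3 and siCARLo-3. Further rises were RELA (1.02), NACA (1.01), CCND3 (0.94), TGFB1 (0.88), the deacetylase gene HDAC1 (0.80) and CDKN2D (0.77). Further falls were the PI3 kinase genes PIK3R1 (-1.17) and PIK3CA (-1.11), RBL1 (-1.11), DBF4 (-1.00), BUB1B (-0.99) and CDK1 (-0.85 ± 0.13, adjusted p = 3.4e-05). CCNE1 (-0.45, adjusted p = 0.0061) fell, MYC (0.21, adjusted p = 0.0046) rose and E2F1 (0.05, adjusted p = 0.80) was not called. With positive control scaling MYC was -0.06 (adjusted p = 0.76), and with 6 reference genes MYC was 0.06 (adjusted p = 0.64).

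CDKN2C, at background in each of the 3 controls, was at least 1.14-fold higher (adjusted p = 0.029) and lost its call without control replicate 1 (adjusted p = 0.068) or 2 (0.13) or siCARLo-5 replicate 3 (0.074), and under positive control (0.15) and reference gene (0.083) scaling and with DESeq2 (0.099). CDKN1B (-0.40, adjusted p = 0.028) lost it without control replicate 1 (0.095) or 3 (0.062) or siCARLo-5 replicate 1 (0.076) or 2 (0.072), at -0.35 to -0.38, and with DESeq2 (-0.40, adjusted p = 0.053).

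Origin licensing and firing genes were lower after siCARLo-5 (1 up, 10 down and 6 not called of 17, 1 and 10 adjusted over the list alone), for example CDC7 (-0.98), CDC6 (-0.86) and CDC45 (-0.84), camera adjusted p = 0.012, but adjusted p = 0.42 with an estimated correlation. G1/S genes were lower (1 up, 11 down and 6 not called of 18, 1 and 11 adjusted over the list alone), camera adjusted p = 0.027, but adjusted p = 0.47 with an estimated correlation. DNA damage genes were lower (0 up, 5 down and 2 not called of 7, 0 and 7 adjusted over the list alone), camera adjusted p = 0.027, but adjusted p = 0.22 with an estimated correlation. The 14-3-3 genes were higher (6 up, 0 down and 1 not called of 7, 6 and 0 adjusted over the list alone), such as SFN, YWHAB (0.60) and YWHAQ (0.53), camera adjusted p = 0.0046, but adjusted p = 0.071 with an estimated correlation. P53 target genes were higher as a list (2 up, 1 down and 1 not called of 4, 2 and 1 adjusted over the list alone), camera adjusted p = 0.027, but adjusted p = 0.13 with an estimated correlation, with MDM2 against the rest. CDK inhibitors (4 up, 1 down and 2 not called of 7, 4 and 1 adjusted over the list alone, camera adjusted p = 0.074) and G2/M genes (4 up, 5 down and 5 not called of 14, 4 and 5 adjusted over the list alone, camera adjusted p = 0.49, MAD2L1 (-0.93) down and CDC25C (0.64) up) were not called, nor were the remaining lists. The spindle checkpoint list had 2 up and 4 down of 10 (list alone 2 and 4, adjusted p = 0.58). Ubiquitin ligase subunits had 4 up and 5 down of 16 (list alone 4 and 5, adjusted p = 0.59). G1 cyclins and pocket proteins had 6 up and 5 down of 16 (list alone 7 and 5, adjusted p = 0.33). TGF-beta and SMAD had 1 up and 2 down of 6 (list alone 1 and 2, adjusted p = 0.85).

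For siCARLo-5, edgeR called 98 of 178 genes (45 up, 53 down), 51 by at least 1.5-fold. Positive controls gave 77 (10 up, 67 down, median of all genes -0.23), 6 reference genes 89 (28 up, 61 down, median -0.10) and the series-wide values 105 (88 up, 17 down, median 0.45). Under positive controls the 14-3-3 genes divided into 1 up and 1 down, against 5 up and 0 down under reference genes. Origin genes stayed lower under both, with 14 and 11 of 17 down, which include the 10 called with TMM, while p53 target genes gave 2 up and 2 down under each. G2/M genes had 0 up and 5 down with positive controls and 1 up and 5 down with reference genes. With positive controls ubiquitin ligase subunits had 0 up and 7 down, and the spindle checkpoint list had 0 up and 4 down under either.

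With siCARLo-7 v2 in HCT116 the largest change was the rise of SFN, the 14-3-3 sigma gene, from 576 to 2546 normalized counts (2.14 ± 0.08, 4.42-fold, adjusted p = 3.8e-13). CDKN1A rose less (0.58 ± 0.08, 1.49-fold, adjusted p = 8.9e-06), and CCND1 (1.07 ± 0.05, 2.10-fold, adjusted p = 2.2e-11), the E-cadherin gene CDH1 (1.20 ± 0.16, 2.30-fold, adjusted p = 6.9e-06) and JUN (1.24) rose as well. The CDK7 partner CCNH (-1.51 ± 0.12, 2.85-fold lower, adjusted p = 1.7e-08), PIK3R1 (-1.44), the DNA repair kinase gene PRKDC (-1.02) and SMC1A (-1.01 ± 0.08, 2.02-fold lower, adjusted p = 1.3e-08) fell. Further rises were PCNA (1.06), RELA (0.96), NFKBIA (0.86), CDC34 (0.84) and ABL1 (0.79). Further falls were CDC23 (-0.96), SKP2 (-0.90), CDC7 (-0.65) and BUB1B (-0.60), the last not called under positive control scaling (-0.47, adjusted p = 0.091). Not called were CCNE1 (0.23, adjusted p = 0.16), CDK1 (-0.07, adjusted p = 0.64) and E2F1 (0.20, adjusted p = 0.27).

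MYC (0.20, adjusted p = 0.011) rose, a call lost without control replicate 3 (0.16, adjusted p = 0.061) and under positive control (0.34, adjusted p = 0.10) and reference gene (0.27, adjusted p = 0.058) scaling. TGFB3 (-1.07, adjusted p = 0.028), above background in 1 of 3 siCARLo-7 v2 libraries, lost its call without control replicate 1 or 2 or any 1 siCARLo-7 v2 replicate (-0.95 to -1.13, adjusted p 0.051 to 0.10). CDC25C (-0.62, adjusted p = 0.020) lost it without control replicate 1 (0.071) or 2 (0.092) or siCARLo-7 v2 replicate 3 (0.076), with positive controls (0.13) and with reference genes (0.0503), at -0.46 to -0.57. CDKN1B (-0.20, adjusted p = 0.27) was called without siCARLo-7 v2 replicate 2 (-0.41, adjusted p = 0.049).

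P53 target genes were higher after siCARLo-7 v2 (4 up, 0 down and 0 not called of 4, 4 and 0 adjusted over the list alone), with GADD45A (0.67) and MDM2 (0.53), camera adjusted p = 2.4e-06, adjusted p = 0.0016 with an estimated correlation. The 14-3-3 genes were higher (5 up, 0 down and 2 not called of 7, 5 and 0 adjusted over the list alone), with YWHAB (0.68) and YWHAZ (0.43), camera adjusted p = 0.0010, adjusted p = 0.026 with an estimated correlation, and 4 of these 5 stayed up under positive control and under reference gene scaling. In the G2/M list (2 up, 8 down and 4 not called of 14, 2 and 8 adjusted over the list alone, camera adjusted p = 0.18) CCNB2 (-0.51), PTTG1 (-0.50) and BUB1 (-0.41) fell and PKMYT1 (0.67) rose. The calls of those falls depended on the scaling, with 0 of 14 down under positive controls and 2 of 14 under reference genes, while the median of the list was -0.41 with TMM, -0.28 with positive controls and -0.34 with reference genes. Fewer falls were also called in the spindle checkpoint list (0 and 2 down) and among G1/S genes (1 down under each). Their medians went from -0.08 and -0.10 with TMM to 0.04 and 0.03 with positive controls. The remaining lists were not called. G1/S genes had 3 up and 4 down of 18 (list alone 3 and 4, adjusted p = 0.69). Origin licensing genes had 2 up and 1 down of 17 (list alone 2 and 1, adjusted p = 0.72). The spindle checkpoint list had 1 up and 4 down of 10 (list alone 1 and 4, adjusted p = 0.69). Ubiquitin ligase subunits had 2 up and 3 down of 16 (list alone 5 and 3, adjusted p = 0.69). CDK inhibitors had 2 up and 0 down of 7 (list alone 1 and 0, adjusted p = 0.72). DNA damage genes had 0 up and 2 down of 7 (list alone 0 and 2, adjusted p = 0.42). G1 cyclins and pocket proteins had 4 up and 2 down of 16 (list alone 4 and 3, adjusted p = 0.69). TGF-beta and SMAD had 0 up and 1 down of 6 (list alone 0 and 0, adjusted p = 0.69). For siCARLo-7 v2 edgeR called 66 of 178 genes (37 up, 29 down), 29 by at least 1.5-fold. Positive controls gave 40 (31 up, 9 down, median of all genes 0.15), 6 reference genes 44 (31 up, 13 down) and the series-wide values 139 (137 up, 2 down, median 0.79).

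**Figure D1:**
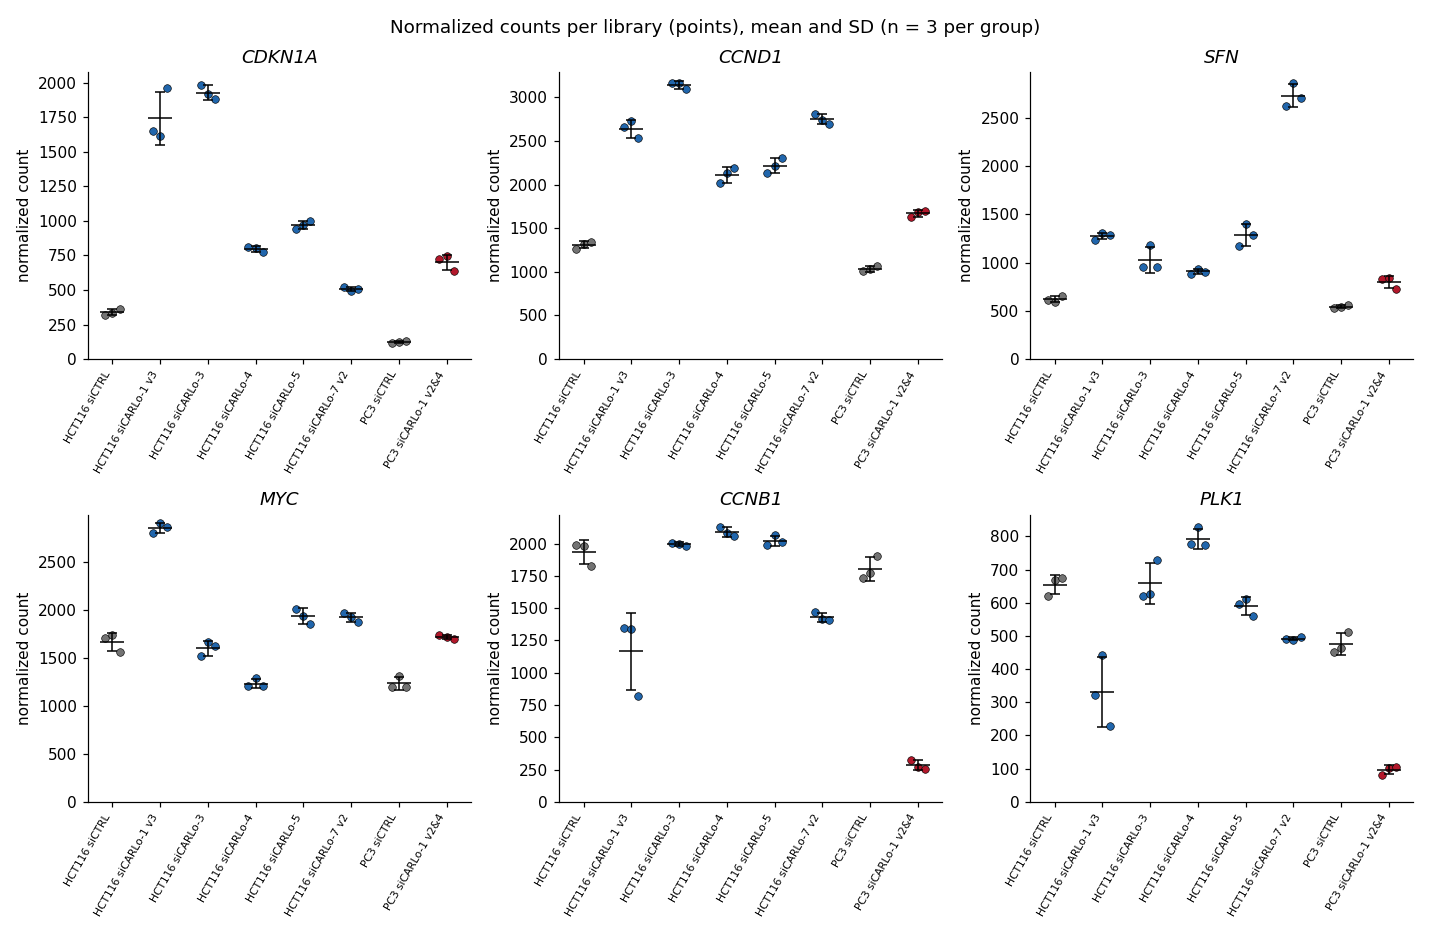
Normalized counts of CDKN1A, CCND1, SFN, MYC, CCNB1 and PLK1 in the 8 groups, where points are libraries, and lines give the mean and SD of 3 libraries, scaled with TMM over all 24. CDKN1A lay between 322 and 362 in the HCT116 controls and between 490 and 1986 in the HCT116 siCARLo libraries, while the signs of CCND1 and MYC in PC3 depended on the scaling (0.79 and 0.57 with TMM, -0.15 and -0.37 with positive controls).

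The F test asked whether the 5 HCT116 siCARLo groups differed from each other, without the control. CDKN1A had the smallest adjusted p (5.6e-13), with means of 1626 in siCARLo-1 v3, 1799 in siCARLo-3, 744 in siCARLo-4, 905 in siCARLo-5 and 471 in siCARLo-7 v2. SFN (adjusted p = 3.4e-11) was highest in siCARLo-7 v2, 1.29 above the mean of the other groups on the log2 scale (adjusted p = 3.7e-12). MYC (6.7e-11) was highest in siCARLo-1 v3 (0.79, adjusted p = 1.3e-10). GADD45A (3.4e-11) was highest in siCARLo-3 (1825 against 969 in siCARLo-1 v3), CDC25B (8.0e-11) in siCARLo-4 (668 against 242 to 408 elsewhere), and CDC23 (6.3e-10) lowest in siCARLo-3 (120). Further genes that differed were YWHAE (3.8e-11), HDAC1 (6.7e-11), MDM2 (3.5e-09), PTTG1 (7.1e-09), E2F1 (3.1e-07), CCND1 (1.7e-07), CCNE1 (5.6e-06), CDK1 (2.7e-04) and CDKN1B (0.013). In direct contrasts MYC was lower in siCARLo-4 than in siCARLo-1 v3 (-1.21, adjusted p = 1.7e-11), and CDKN1A was not called between siCARLo-3 and siCARLo-1 v3 (0.15, adjusted p = 0.085).

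By edgeR 154 of 178 genes were called in the F test among siCARLo groups. Within the set of siCARLo-1 v3, siCARLo-3 and siCARLo-4, which share equal positive control sums, 119 genes differed, and siCARLo-7 v2 differed from siCARLo-5 of its set in 93 (53 up, 40 down). The latter split was 97 up and 10 down with positive controls (median of all genes 0.51), 79 up and 18 down with 6 reference genes (median 0.32) and 90 up and 12 down in the series-wide table (median 0.44). Both comparisons within a set were chosen after the data were seen. The ratio of positive controls A and B also differed inside a set. It was 2.42, 2.69 and 2.19 in siCARLo-1 v3, siCARLo-3 and siCARLo-4, and 2.37 and 2.90 in siCARLo-5 and siCARLo-7 v2. A shared set thus does not exclude a shift of single probes.

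Genes changed the same way in all 5 HCT116 siCARLo groups numbered 10. CDKN1A (1.49 to 5.69-fold), SFN (1.47 to 4.42), JUN (1.52 to 3.37), CCND1 (1.62 to 2.40), the tyrosine kinase gene ABL1 (1.38 to 1.73), ANAPC2 (1.36 to 1.74) and the checkpoint gene MAD1L1 (1.30 to 1.47) rose. CDC7 (1.57 to 2.50-fold lower), SMC1A (1.35 to 2.22-fold lower) and BUB1B (1.39 to 1.99-fold lower) fell. The fall of SMC1A followed the scaling sets, with -0.43 to -0.47 in siCARLo-1 v3, siCARLo-3 and siCARLo-4 and -1.15 and -1.01 in siCARLo-5 and siCARLo-7 v2. ABL1 (adjusted p = 0.066), ANAPC2 (0.076), MAD1L1 (0.72) and CDC7 (0.055) were not called as different among the 5 groups. Opposite calls were common as well, with 35 genes up in at least 1 group and down in at least 1 other. The 5 comparisons share their 3 controls, and 100 simulations with unchanged groups gave 0 such genes, while independent lists of the same sizes would share 0.170. Log2 fold changes of pairs of groups correlated with a mean r of 0.484, against 0.501 from the shared controls alone, while the mean covariance was 0.131 against 0.0152, a difference of 0.116. The 3 controls cannot be divided into parts of at least 2, so part of the excess may come from the shared controls. Only 4 genes were called the same way with positive control scaling (2 up, 2 down), 4 with 6 reference genes (3 up, 1 down) and 10, all up, in the series-wide table.

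**Figure D2:**
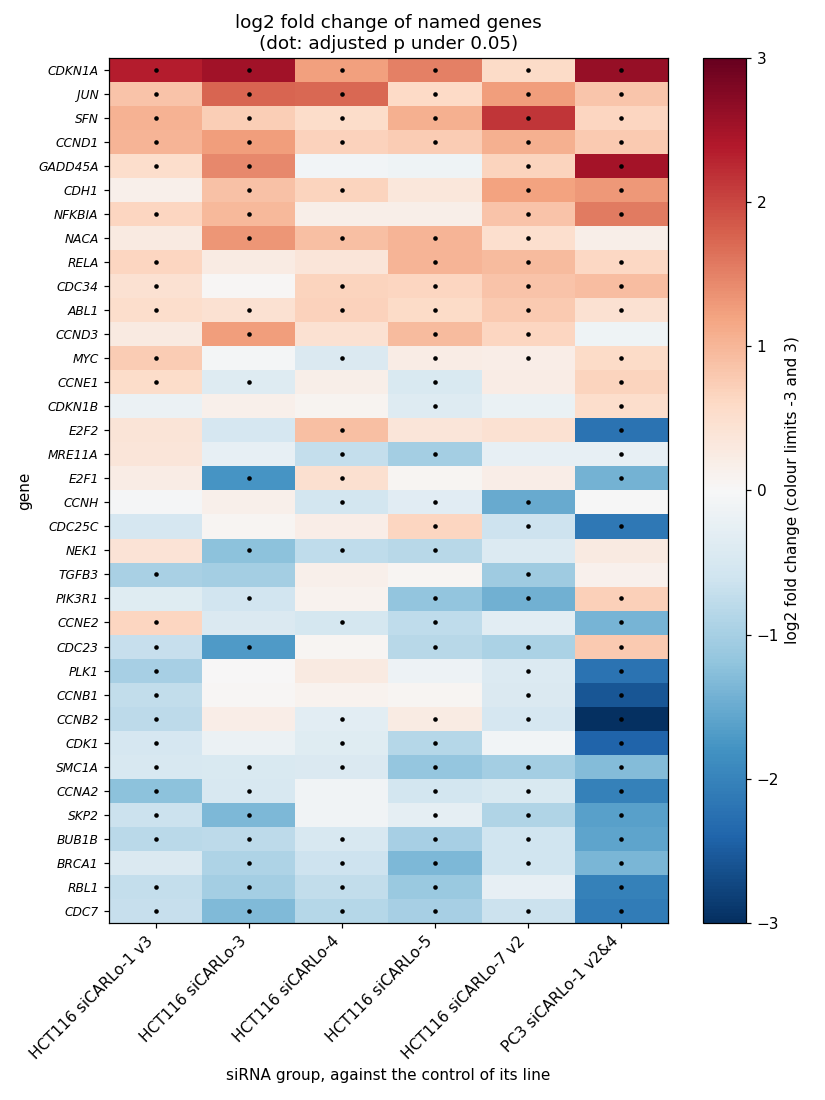
Log2 fold changes of 36 genes in the 6 comparisons of a siCARLo group with its control, as colour from -3 to 3, with a dot where the adjusted p was under 0.05. CDKN1A was called higher in all 6 columns (0.58 in siCARLo-7 v2 to 2.61 in PC3) and CDC7 lower in all 6 (-0.65 to -2.11), whereas the signs of CCND1 and MYC in PC3 turned with positive control scaling (-0.15 and -0.37).

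What siCARLo-1 v2&4 changed in PC3 was the question of the next comparison. Genes that drive mitosis fell, namely the cyclin B genes CCNB2 (-3.07 ± 0.08, 8.38-fold lower, adjusted p = 5.8e-07) and CCNB1 (-2.58 ± 0.10, 5.97-fold lower, adjusted p = 2.1e-06), their kinase CDK1 (-2.41 ± 0.07, 5.33-fold lower, adjusted p = 8.4e-07), and PLK1 (-2.21 ± 0.12, 4.62-fold lower, adjusted p = 1.0e-05). CDKN1A rose from 144 to 883 normalized values (2.61 ± 0.08, 6.09-fold, adjusted p = 1.1e-06) and the stress gene GADD45A rose too (2.49 ± 0.06, 5.60-fold, adjusted p = 5.8e-07). The S phase regulators E2F1 (-1.41 ± 0.10, 2.67-fold lower, adjusted p = 3.0e-05), CCNA2 (-2.03 ± 0.05, 4.07-fold lower, adjusted p = 5.8e-07) and CDC7 (-2.11 ± 0.05, 4.30-fold lower, adjusted p = 5.8e-07) fell. Further rises were the transcription factor genes CREB3L1 (2.48) and CREB3 (1.63), HDAC5 (1.98), NFKBIA (1.55 ± 0.06, adjusted p = 2.1e-06), the F-box gene FBXW7 (1.46), POLR1C (1.35) and CDH1 (1.30), the last not called under positive control scaling (0.36, adjusted p = 0.064). Further falls were the APC/C activator CDC20 (-2.15) and RBL1 (-2.03), and E2F2 (-2.20) and CDC25C (-2.14), each above background in 1 of 3 siCARLo-1 v2&4 libraries. CCND1 (0.79 ± 0.05, adjusted p = 2.3e-05), MYC (0.57 ± 0.06, adjusted p = 1.8e-04), CDKN1B (0.53, adjusted p = 0.0098) and CCNE1 (0.68, adjusted p = 2.8e-04) rose with TMM, but with positive control scaling CCND1 was -0.15, MYC -0.37, CCNE1 -0.25 and CDKN1B -0.39, the last called lower (adjusted p = 0.047).

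Each tested G2/M gene was lower in PC3 siCARLo-1 v2&4 (0 up, 14 down and 0 not called of 14, 0 and 14 adjusted over the list alone), camera adjusted p = 6.0e-07 and adjusted p = 0.042 with an estimated correlation, and all 14 stayed lower under each of the 4 scalings of these values. Origin licensing genes were lower (0 up, 13 down and 4 not called of 17, 0 and 13 adjusted over the list alone), such as MCM6 (-1.82), MCM3 (-1.77) and MCM2 (-1.60), camera adjusted p = 4.1e-04, but adjusted p = 0.083 with an estimated correlation. G1/S genes were lower (3 up, 14 down and 1 not called of 18, 3 and 14 adjusted over the list alone), for example SKP2 (-1.63), camera adjusted p = 0.0013, but adjusted p = 0.11 with an estimated correlation. The spindle checkpoint list was lower (1 up, 9 down and 0 not called of 10, 1 and 9 adjusted over the list alone), with BUB1 (-1.86), PTTG1 (-1.75) and ESPL1 (-1.75), camera adjusted p = 0.0019, but adjusted p = 0.083 with an estimated correlation. P53 target genes were higher (4 up, 0 down and 0 not called of 4, 4 and 0 adjusted over the list alone), with MDM2 (0.80) and SFN (0.65). The camera adjusted p was 0.017, but 0.11 with an estimated correlation, and 2 of 4 stayed up with positive control scaling. The list name does not show that p53 acted in PC3, which was not tested. DNA damage genes (1 up, 4 down and 2 not called of 7, 1 and 4 adjusted over the list alone, camera adjusted p = 0.19) held BRCA1 (-1.37) and CHEK2 (-1.08) down and CHEK1 (0.37) up.

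Ubiquitin ligase subunits in PC3 (9 up, 2 down and 5 not called of 16, 8 and 2 adjusted over the list alone, camera adjusted p = 0.068), with CDC16 (0.93) and ANAPC5 (0.82), and CDK inhibitors (4 up, 0 down and 2 not called of 6, 5 and 0 adjusted over the list alone, camera adjusted p = 0.068), with CDKN2B (1.01), were called without siCARLo-1 v2&4 replicate 3 (adjusted p = 0.0498 each). TGF-beta and SMAD (5 up, 0 down and 1 not called of 6, 5 and 0 adjusted over the list alone, camera adjusted p = 0.068), with SMAD3 (0.92) and SMAD4 (0.66), were not called. These 3 lists turned with the scaling, since positive controls gave 1 up and 10 down, 1 up and 4 down, and 0 up and 3 down, and so did G1 cyclins with pocket proteins (0 up, 13 down) and 14-3-3 proteins (0 up, 6 down). The remaining lists were not called. G1 cyclins and pocket proteins had 8 up and 5 down of 17 (list alone 8 and 5, adjusted p = 0.82). 14-3-3 proteins had 3 up and 2 down of 7 (list alone 3 and 2, adjusted p = 0.82), where YWHAB (-1.64) fell. By limma 136 of 179 genes were called in PC3 (72 up, 64 down), 87 by at least 1.5-fold. Positive control scaling gave 141 (9 up, 132 down, median of all genes -0.85), 6 reference genes 135 (92 up, 43 down, median 0.32) and the series-wide values 163 (6 up, 157 down, median -1.07).

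**Figure D3:**
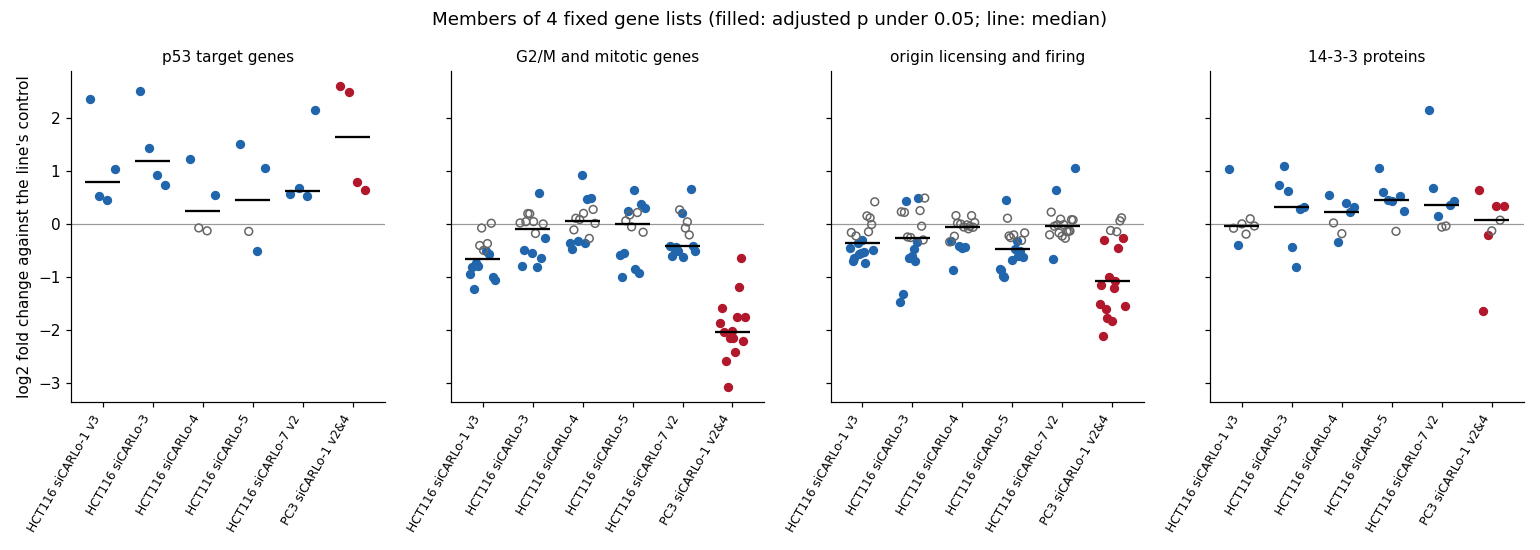
Log2 fold changes of the members of the p53 target, G2/M, origin licensing and 14-3-3 lists in each comparison with a control, where filled points are called genes and lines are list medians. All 14 G2/M genes were lower in PC3 (median -2.02), and all 4 p53 target genes were higher in 4 of the 6 comparisons, while the 14-3-3 rise in siCARLo-5 was not called with an estimated correlation (adjusted p = 0.071) and became 1 up and 1 down with positive control scaling.

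Whether siCARLo-1 acted alike in the 2 lines was tested as the HCT116 effect minus the PC3 effect, though siRNA, dose and line all differ. The mitotic genes CCNB2 (2.35 ± 0.15, adjusted p = 5.6e-10), CDK1 (2.0 ± 0.19, adjusted p = 6.4e-08) and CCNB1 (1.91 ± 0.19, adjusted p = 9.6e-08) fell less in HCT116 than in PC3. In the fits of each line CCNB2 was -0.79 against -3.07, CDK1 -0.50 against -2.41 and CCNB1 -0.73 against -2.58. Positive differences were also found for CDC20 (1.77), CDC25C (1.78) and CDC25B (2.04), which fell in PC3 and were not called in HCT116. The S phase genes E2F2 (2.58), CCNE2 (2.14), PCNA (1.99) and E2F1 (1.73) differed in the same direction, where E2F2 and CDC25C lay above background in 1 of 3 PC3 siCARLo-1 v2&4 libraries. GADD45A (-1.86 ± 0.11, adjusted p = 1.5e-10), CDK7 (-1.40) and CDC23 (-1.37) had negative differences. HDAC5 (-1.41), CREB3 (-1.33), MAPK8 (-1.18), NFKB1 (-1.14) and CDH1 (-1.13) had them with TMM, but were not called with positive control scaling (adjusted p 0.053 to 0.26). CDKN1A (-0.16 ± 0.11, adjusted p = 0.26) and CCNE1 (-0.05, adjusted p = 0.84) were not called, but positive control scaling called CCNE1 (0.72, adjusted p = 0.037). Without siCARLo-1 v3 replicate 3, CDKN1A was called (-0.29, adjusted p = 0.012), as it was with 6 reference genes (-0.38, adjusted p = 0.017), but positive control scaling gave 0.62 (adjusted p = 0.025). CDKN1B (-0.62, adjusted p = 0.012) was called, at 0.15 with positive control scaling. MYC (0.30, adjusted p = 0.0059) and CCND1 (0.32, adjusted p = 0.0014) lost their calls without HCT116 control replicate 2 (0.20, adjusted p = 0.14, and 0.20, adjusted p = 0.072) and with 6 reference genes (adjusted p = 0.68 and 0.62).

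By limma 102 of 184 genes were called for the difference (60 positive, 42 negative). Of these, CCNB3 and CREB3L1 lay at background in every library of 1 line, so no value of the difference is given for them. Positive controls gave 116 (112 and 4, median of all genes 0.85), 6 reference genes 86 (34 and 52, median -0.14) and the series-wide values 158 (157 and 1, median 1.39). Among 173 genes tested in both lines, 23 were called up in both (11.7 for independent lists) and 30 down in both (15.7). Another 8 were called in opposite directions, and the effects correlated with r = 0.602. This overlap was counted with TMM only. With positive control scaling the median of all PC3 genes was -0.85 and most PC3 calls were falls, so the number of shared rises depends on the scaling.

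The PC3 control was compared with the HCT116 control for the baseline of the 2 lines, which also differ in siRNA dose. The genes CDKN1A (-1.47 ± 0.08, adjusted p = 5.9e-12) and MDM2 (-1.56) were lower in PC3. Higher there were TGFB2, with 2118 against 13.3 (7.22 ± 0.21, 149-fold, adjusted p = 7.4e-16), the NF-kappaB inhibitor gene NFKBIA (2.26 ± 0.09, 4.80-fold, adjusted p = 9.4e-14), JUN (2.24), DTX4 (2.50) and, among CDK inhibitors, the gene CDKN2B (1.95), where TGFB2 and DTX4 were above background in 1 of 3 HCT116 controls. CCND2 was at least 60.1-fold, SHH at least 28.5-fold, CCNA1 at least 9.62-fold, TBX2 at least 2.11-fold, TWIST1 at least 1.98-fold and CREB3L1 at least 1.83-fold higher, each with HCT116 at background. CDK1 (1.49 ± 0.13, adjusted p = 1.1e-08) and E2F1 (1.36 ± 0.14, adjusted p = 7.5e-08) were higher and CCNE1 (-1.60), CDKN1B (-0.60), PIK3R1 (-1.60), CDK7 (-1.51), SMAD4 (-1.40), TFDP2 (-1.12) and HDAC4 (-1.08) lower. MYC (-0.43, adjusted p = 3.7e-06) and CCND1 (-0.34, adjusted p = 1.7e-05) were lower, but not called with positive control scaling (-0.32, adjusted p = 0.081, and -0.22, adjusted p = 0.23).

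No list was called between the lines (camera adjusted p 0.63 to 0.99). Members called up and down were 7 and 4 of 18 for G1/S genes, such as RBL1 (1.40) and CDC25A (1.40), 6 and 5 of 17 for origin licensing, 4 and 7 of 14 for G2/M genes, 2 and 4 of 10 for the spindle checkpoint and 3 and 7 of 16 for ubiquitin ligase subunits. They were 3 and 2 of 7 for CDK inhibitors, 1 and 2 of 4 for p53 target genes (GADD45A (0.18) up), 1 and 3 of 7 for DNA damage, 5 and 5 of 17 for G1 cyclins and pocket proteins, 4 and 2 of 6 for TGF-beta and SMAD, and 1 and 3 of 7 for 14-3-3 proteins, where YWHAB (1.43) was higher. Adjusted over the list alone, p53 target genes had 1 up and 3 down, and the other lists kept their counts. By limma 126 of 184 genes were called (65 up, 61 down). Scaling to positive controls gave 93 (60 up, 33 down, median of all genes 0.13), 6 reference genes 111 (44 up, 67 down, median -0.13) and the series-wide values 145 (138 up, 7 down, median 0.85).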

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

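Tests of depth, of earlier scaling and of shared sets in PC3, and the division of regroupings by whether the PC3 groups stayed whole, were chosen only after the results were seen. The comparison of siCARLo-1 effects stands out because the 2 lines differed in 102 of 184 genes (HCT116 siCARLo-1 v3 effect minus PC3 siCARLo-1 v2&4 effect). The largest positive differences on the log2 scale were E2F2 2.58, CCNB2 2.35, CCNE2 2.14, CDC25B 2.04, CDK1 2.0, PCNA 1.99, CCNB1 1.91, CDC25C 1.78, CDC20 1.77 and E2F1 1.73, where E2F2 and CDC25C lay above background in 1 of 3 PC3 siCARLo-1 v2&4 libraries. Among the largest negative ones were GADD45A -1.86, HDAC5 -1.41, CDK7 -1.40, CDC23 -1.37, CREB3 -1.33, MAPK8 -1.18, NFKB1 -1.14 and CDH1 -1.13. Of the fixed genes, MYC 0.30, CCND1 0.32 and CDKN1B -0.62 differed. Of the 102 genes 2 lay at background in every library of 1 line, so no value is given for them.

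Regrouping does not by itself separate this difference from the size of the PC3 effect. With labels exchanged within each line, 5 of 100 groupings, the real one included, gave at least 102 genes, and the highest other grouping gave 111. All 4 others as large kept the PC3 groups whole (9 such groupings), while the 90 that mixed the PC3 libraries reached at most 17. The count thus depends on the size of the PC3 effect, and chance assignment of the libraries is not excluded by it. Another way of counting mirrored groupings was tried and dropped, because turning over the groups of 1 line alone changes what the contrast measures. Line, siRNA and dose differ together and cannot be told apart, and the RNA loaded per library was not tested.

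All 14 tested G2/M genes fell in PC3 with siCARLo-1 v2&4. The tables argue against lower depth, since genes with the same level in the control should then fall as much. The G2/M genes lay a median of 1.97 below the 10 genes nearest to each in level (-1.97), and all 14 lay below theirs (highest -1.06). The SD of this difference over the other single genes was 0.91. The fewest lower genes over 4 scalings was 14. Each scaling divides a library by 1 factor, so an earlier factor per library cancels. That count thus decides nothing about the earlier scaling by the authors. The groups share 0 scaling sets, so a shift between runs that the sets may mark cannot be told apart from the siRNA for these genes. Off-target effects of the siRNA and the higher dose in PC3 are untested.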

How the results depend on the processing

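Scaling by 6 reference genes, merging 2 control libraries, edgeR on the whole numbers of fits with PC3, and the comparisons within a scaling set were tests chosen only after the data were seen. Counts of called genes moved by more than 1.5-fold in 6 cases, each under another scaling. Positive control scaling gave 46 genes in place of 73 for siCARLo-1 v3, 40 in place of 66 for siCARLo-7 v2 and 4 in place of 10 for genes called the same way in all 5 groups, which also numbered 4 with 6 reference genes. The series-wide table gave 139 for siCARLo-7 v2 and 158 in place of 102 for the difference between the siCARLo-1 effects. In that table each set of libraries is scaled to its own positive control sum, so groups from different sets are shifted as a whole.

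Among 2710 settings of 216 named gene results, 2614 kept the call or its absence, 82 lost the call and 6 gained it. Another 8 turned in sign with a call in either fit, all with positive control scaling. Turns in sign without a call in either fit count among the 2614, and F test results carry no sign. In siCARLo-5 MYC became -0.063. In PC3 MYC became -0.37, CDKN1B -0.39, CCND1 -0.15 and CCNE1 -0.25. In the difference of effects CDKN1A became 0.62, CDKN1B 0.15 and CCNE1 0.72, the first and last of these with a call. The median of all PC3 genes went from 0.076 to -0.85 under that scaling, which moves these genes by construction, and the lower number of endogenous molecules per positive control count (5.96 against 10.4) was not explained, so whether the fall in total signal reflects the RNA loaded was not tested.

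Leaving out 1 library gave 64 to 76 genes for siCARLo-1 v3, 84 to 89 for siCARLo-3, 52 to 61 for siCARLo-4, 87 to 97 for siCARLo-5, 48 to 57 for siCARLo-7 v2 and 123 to 136 for PC3. The ranges were 147 to 158 for the F test, 7 to 12 for genes called the same way, 90 to 116 for the difference of effects and 115 to 121 for the lines. They were 110 to 133 among siCARLo-1 v3, siCARLo-3 and siCARLo-4, and 79 to 86 for siCARLo-7 v2 against siCARLo-5. With HCT116 control libraries 1 and 2 as 1 library the counts were 65, 87, 56, 93 and 54 for siCARLo-1 v3, siCARLo-3, siCARLo-4, siCARLo-5 and siCARLo-7 v2, and 8 for genes called the same way.

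Pairing libraries by replicate number was checked through correlations of residuals, which had a median of -0.05 over 45 pairs of HCT116 libraries, 14 of them over 0.1, and 0 of 3 over 0.1 in PC3, so no block was fitted in the comparisons given. With a replicate block the counts were 69 for siCARLo-1 v3, 92 for siCARLo-3, 63 for siCARLo-4, 96 for siCARLo-5, 59 for siCARLo-7 v2, 133 for PC3, 151 for the F test, 8 for genes called the same way, 96 for the difference of effects and 125 for the lines. The block gave 119 and 89 for the comparisons within a set.

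Of 66 list results 16 were called, and 11 of these were lost and 5 kept with an estimated correlation in place of the preset one. The p53 target list in siCARLo-1 v3, siCARLo-3 and siCARLo-7 v2, the 14-3-3 list in siCARLo-7 v2 and the G2/M list in PC3 were kept. Fry, which asks whether a list changed at all, lost 0 and gained 23. Leaving out 1 library lost 0 list calls and gained 6.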

Other observations

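The p53 target genes on the panel did not move as one. Whether p53 itself drove any of their changes was not tested in either line. MDM2 rose with siCARLo-3 (0.93) and fell with siCARLo-5 (-0.50), while CDKN1A rose with each of them. CDKN1A rose 5.14-fold with siCARLo-1 v3 in HCT116 and 6.09-fold with siCARLo-1 v2&4 in PC3, where its baseline was lower (-1.47). Which rise is larger depends on the scaling, since the HCT116 effect minus the PC3 effect was -0.16 with TMM (adjusted p = 0.26) and 0.62 with positive control scaling (adjusted p = 0.025).

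Tests of the control's own scaling set, and both tests of siCARLo-1 v3 replicate 3, were chosen only after the results were seen. The same 10 genes changed alike in all 5 HCT116 siCARLo groups. The tables argue against the 3 shared controls alone as the source, since 0 of 100 simulated draws of unchanged groups held as many. Those draws held no changed genes, so they cannot show how much the shared controls add where groups do change. A probe-specific shift between the 2 sets that hold the siCARLo groups cannot be told apart for these genes. Of the 9 other divisions of the groups into 3 and 2, 7 gave as many genes as the real one (85), a count that decides nothing since groups within a set already differed in 119 and 93 genes. A shift of the control's own run cannot be told apart either, because 0 siCARLo groups lie in the scaling set of the control. The mean ratio of positive controls A and B, which no siRNA acts on, was higher in each siCARLo group (2.19 to 2.90) than in the control (2.01). By library the ratios overlapped. Control replicate 3 (2.184) lay above siCARLo-1 v3 replicate 3 (2.151) and siCARLo-4 replicates 2 (2.177) and 3 (2.151). Shifts of single probes may thus add to these folds, and a shared response to transfection of an active siRNA is untested.

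Replicate 3 of HCT116 siCARLo-1 v3 lay apart from its group, with a chi-square per degree of freedom of 56.2 and 50.2 against replicates 1 and 2, which differed by 2.60, while pairs in the other groups gave 1.18 to 4.46. GAPDH took 32.1% of its counts against 20% and 19.7%, and PGK1 8.25% against 4.02% and 3.86%, and CDC20 (-1.03), PCNA (-1.03) and CHEK1 (-0.93) were lower than in the others. The tables argue against these 2 genes pushing the others down as the whole cause, since that would move all others by 1 factor. Without GAPDH and PGK1 the chi-square per degree of freedom was still 10.5 and 12.7 against replicates 1 and 2, and at most 4.21 within the other groups. They also argue against a library of another group under a wrong label. With all genes the lowest value of replicate 3 was against a siCARLo-3 library (42.9). That was lower than against its own replicates, but still far outside the range within groups. Such values grow with the counts compared. Totals were 55893 to 92559 in siCARLo-3 and 130238 and 83850 in siCARLo-1 v3 replicates 1 and 2, so the lower value may reflect depth. Without GAPDH and PGK1 the lowest value against another group was 26.2, above those against its own replicates. What set it apart, such as culture state or RNA quality, stays open. Without it 74 genes were called in place of 73, with 63 shared, and 8 of 14 G2/M genes fell.

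Regrouping 3 against 3 libraries has 10 ways, too few for a share under 0.05, and in each case 1 grouping, the real one, gave as many genes as it did. For siCARLo-1 v3 the real count was 73 and the highest other 9, and for siCARLo-7 v2 against siCARLo-5 they were 93 and 1. The highest other was 0 for siCARLo-3 (93), siCARLo-4 (63), siCARLo-5 (98), siCARLo-7 v2 (66), PC3 siCARLo-1 v2&4 (136) and the controls of the 2 lines (126). Of 100 groupings, 1, the real one, gave as many for the F test (154, highest other 17). The same held for the F test among siCARLo-1 v3, siCARLo-3 and siCARLo-4 (119, highest other 69). It also held for genes called the same way (10, highest other 0). Where groups differ, mixing their libraries raises the spread within drawn groups, which lowers the other counts. The regroupings thus show that libraries of a group resemble each other. They cannot tell an effect of the siRNA from a shift between runs.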
